A study of Mus musculus with 6 samples.

How the data were processed

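Total RNA from whole mouse ovaries was labelled with biotin and hybridised to single-colour Affymetrix arrays, per the labels' protocols. There were 6 arrays, 2 for each of 3 groups named in the labels: 26-day-old wild type, 26-day-old Kras mutant and 3-month-old Kras mutant mice. The authors deposited 1 intensity per probe set and array. RMA and the affy package were named in the submitters' processing notes, with no version. The deposited intensity values were whole numbers on a linear scale, not the log2 scale that RMA usually gives. How they were put back on a linear scale, and whether the 6 arrays were summarised in 1 run, is not given in the sources used here. No detection calls were used. Median intensity was 137 to 141 on the 6 arrays, but the 95th percentile was 3398 to 3552 on the 26-day arrays and 4276 to 4306 on the 3-month arrays, so the value distributions were not the same.

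Intensities were converted to log2 with nothing added and were not normalized again. Differences are on this scale, and whole-number rounding makes low intensities coarse. Of 45101 probe sets, 64 were array controls. The platform annotation listed 35890 probe sets, 34958 with 1 gene and 932 with several, and 9211 were not listed and stayed unnamed. Symbols were updated through Entrez identifiers in a table of RefSeq genes, where 18033 of 18195 genes were found. Each gene was represented by the probe set with the highest mean over the 6 arrays among those that name only that gene. Probe sets of 1 gene can disagree. In the 3-month against 26-day mutant comparison 1289 of 9009 genes with several probe sets had significant calls in opposite directions. Of the genes named in the report these include Cyp11a1, Foxo3 and, in the 3-month mutant against the wild type, Gpnmb and Pck1.

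Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 6 arrays with group means and no covariate, which left 3 residual degrees of freedom and 3.48 prior degrees of freedom. P-values were 2-sided and adjusted by Benjamini-Hochberg over all 18195 genes, with a threshold of 0.05 and no minimum fold. The comparisons were mutant against wild type at 26 days, the 3-month mutant against the 26-day mutant, and the 3-month mutant against the 26-day wild type. Gene lists, 26 in number with 517 of 566 genes measured, were tested with camera at a preset correlation between genes of 0.01, adjusted over the 26 lists of a comparison. Members were counted over all genes and adjusted over the list alone. Camera with an estimated correlation and fry served as alternatives. With an estimated correlation camera's p-values rest on the 3 residual degrees of freedom, so only a very large shift can pass. No list passed that way in any comparison, so this setting cannot tell firm list calls from weak ones. The 49 list genes without a probe set of their own, among them Cyp19a1 and Lhcgr, were not analysed here.

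The groups, the tests, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 10 largest rises and the 10 largest falls among genes past the threshold whose arrays do not overlap between the groups (5 of each for the 3-month mutant against the wild type). For each list that passed its test or had several members past the threshold it took up to 4 members past the threshold with the largest difference. Predicted genes and unnamed clones were skipped, and Kras and the control genes were always taken. Other genes given as values in the text were chosen after their values were seen.

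The scripts were tested on simulated data with the real group sizes and 18195 genes. Each run planted 67, 67 and 66 genes changed by log2 1, 2 and 4. With fewer changed genes the adjusted threshold is stricter. The recovered shares are thus no measure of power in the real 26-day comparison, where 5 genes passed. In the 26-day comparison genes changed by log2 1, 2 and 4 were recovered in 67.2%, 95.5% and 98.5% of cases, and 8 of 182 calls were false. For the 3-month against the 26-day mutant the shares were 58.2%, 98.5% and 100%, with 12 of 183 calls false, and for the 3-month mutant against the wild type they were 73.1%, 95.5% and 100%, with 8 of 187 false. Alternatives covered the replicate number as a block, each array left out, only the 2 groups compared, a trend and a robust variance prior, 2 further normalizations, a filter on dim genes, other choices of probe set and stricter thresholds. Where 1 array was left out, the lone array of its group was assumed to vary like the other groups. For the 26-day comparison, leaving out a 3-month array changes no difference and gives the same fit as only the 2 groups compared. A value of 16 added before log2, crossed replicate numbers and, for named genes, the mean of probe sets were added after seeing the data.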

Results

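Gene expression was measured in whole mouse ovaries with 6 single-colour Affymetrix arrays, 2 for each of 3 groups. The groups were wild type mice aged 26 days, Kras mutant mice of that age and Kras mutant mice aged 3 months. The mutant mice carried a conditional Kras (G12D) allele, which encodes a RAS protein that stays active, and Amhr2-Cre, a recombinase expressed in granulosa cells and in some other cells of the ovary. No wild type ovaries of 3 months were analysed here. The labels number the replicates but do not say whether they are separate animals, so p-values measure only the spread between these samples, which may be technical. Median intensity per array was 137 to 141, and the number of arrays, 2 per group, limits the precision of every value. Intensities were compared as log2 values for 18195 genes, and each log2 difference is given with its standard error (SE) from limma. Kras itself could not be followed, because no probe set was annotated to Kras alone. The allele differs by 1 amino acid, so its transcript level would not check the genotype.

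The first comparison asked how the mutant ovary differed from the wild type ovary at 26 days. Of the genes of ERK feedback 2 of 27 passed the test, both higher in the mutant, and of the smooth muscle markers 1 of 14 passed, lower in the mutant. As lists, the first was higher and the second lower by camera and by fry (fry adjusted p = 0.00678 and 0.00902). Both camera calls were lost with an estimated correlation (adjusted p = 0.0940 for each with an estimated correlation). For the ERK list the estimated correlation was -0.02, below the preset 0.01, so correlation between its genes does not account for that loss. This setting also rests on only 3 residual degrees of freedom. A call lost under it therefore need not come from correlation between genes. Etv5, an ETS transcription factor induced by ERK signalling, was 3.99-fold higher (log2 difference 2.00 ± 0.14 SE, n = 2 per group, limma adjusted p = 0.0324). Dusp4, a phosphatase that dampens ERK, was 3.67-fold higher (1.87 ± 0.16, limma adjusted p = 0.0452). Clec14a, an endothelial membrane protein, was 3.20-fold higher (1.68 ± 0.14, limma adjusted p = 0.0440). Stc1, which encodes the secreted glycoprotein stanniocalcin, fell by 1.94 ± 0.13 on the log2 scale (limma adjusted p = 0.0324). Lmod1, a smooth muscle actin-binding protein, fell by 1.34 ± 0.11 (limma adjusted p = 0.0440). Taking the mean over a gene's probe sets, an alternative chosen after the data were seen, put Etv5 at 1.29 and Stc1 at -1.05, where Stc1 did not pass (limma adjusted p = 0.0867, and 0.00653 to 0.440 over all alternatives). These 5 were the only genes of 18195 past an adjusted p of 0.05, and for each of them both mutant arrays lay on the same side of both wild type arrays. At an unadjusted p under 0.05 there were 1400 genes. Arrays of the 2 groups did not overlap for 36.0% of genes, where chance gives 33.3%. The limma count was 0 when any one of the 6 arrays was left out (832 to 1710 genes at an unadjusted p under 0.05) and 0 with only the 26-day arrays (1710 genes).

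**Figure D1:**
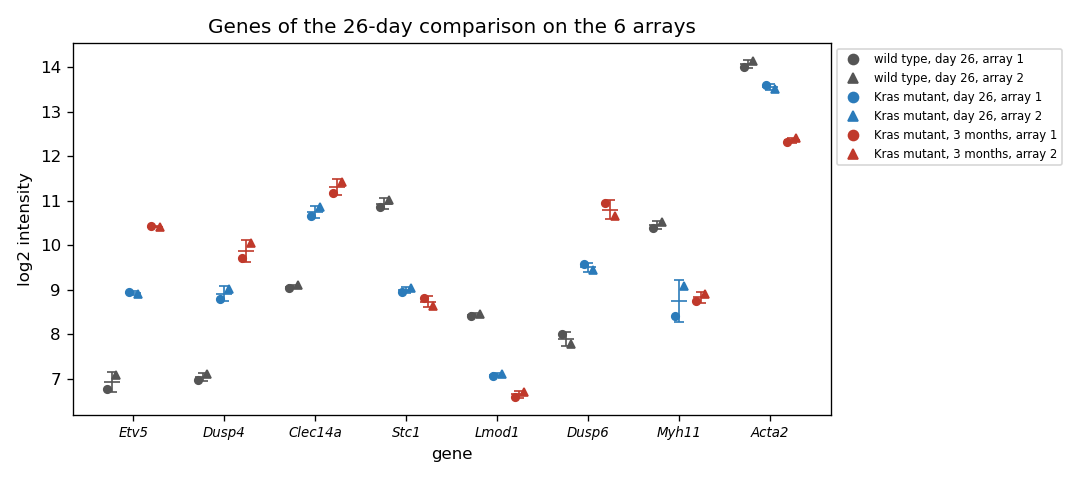
Log2 intensity (vertical axis) of the 5 genes that passed the test at 26 days and of Dusp6, Myh11 and Acta2 on the 6 arrays; symbols are arrays, horizontal ticks are group means and bars are 1 SD (n = 2). Etv5 rose from 6.93 in the wild type to 8.93 in the 26-day mutant and lay at 10.42 in the 3-month mutant.

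Of 26 gene lists, 6 passed camera at 26 days. By fry, which does not compare a list with other genes, the ERK and smooth muscle lists passed (adjusted p = 0.00678 and 0.00902). The endothelial, stroma, adipocyte and granulosa lists did not (fry adjusted p = 0.296, 0.342, 0.296 and 0.559). The members named at 26 days that did not pass over all genes were chosen after their values were seen. The list of ERK pathway feedback and target genes was higher (limma camera adjusted p = 9.80e-09; adjusted p = 0.0940 with an estimated correlation), with 2 of 27 measured members past the threshold over all genes. Adjusted over the list alone, 9 members were higher and 1, Myc, was lower. They included the ERK phosphatase Dusp6 at 1.60 ± 0.15 (limma adjusted p = 0.0613 over all genes), the inhibitors Spred2 at 0.79 ± 0.13 and Spry1 at 0.76 ± 0.16, and Ier3 at 0.94 ± 0.19. The smooth muscle list was lower (camera adjusted p = 6.08e-16; adjusted p = 0.0940 with an estimated correlation), with 1 of 14 members, Lmod1, past the threshold and 8 lower when adjusted over the list alone. Among those 8 the contractile genes Cnn1, Myh11 and Actg2 had log2 differences of -1.73 ± 0.17, -1.72 ± 0.22 and -1.63 ± 0.20, and Acta2 had -0.51 ± 0.11. As means over probe sets Myh11 was at -0.83 and Spred2 at 0.39. Oviduct and cilia markers had a median log2 difference of 0.12 between the same groups, with no member past the threshold over all genes. That median changed sign with the arrays, from -0.14 without wild type replicate 1 to 0.42 without wild type replicate 2. The list passed camera as higher without wild type replicate 2 or Kras_d26 replicate 1 (means of 0.55 and 0.33). With all arrays its adjusted p was 0.279 by camera, 0.913 by camera with an estimated correlation and 0.966 by fry.

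Cell type lists other than smooth muscle shifted by smaller amounts at 26 days. For the endothelial list (camera adjusted p = 6.67e-10; adjusted p = 0.535 with an estimated correlation) 19 of 20 members had a positive difference, the median was 0.41, and none passed over all genes or adjusted over the list alone. The list of fibrous stroma and collagen genes was higher (camera adjusted p = 1.93e-07, median 0.29; adjusted p = 0.563 with an estimated correlation), with no member past the threshold over all genes and, adjusted over the list alone, 6 higher and 1 lower. Pdgfra, a receptor of stromal cells, lay at 1.00 ± 0.16, and Mfap5, a microfibril protein, at -1.10 ± 0.16. The adipocyte list was higher (camera adjusted p = 0.000795; adjusted p = 0.535 with an estimated correlation), with 5 of 12 members higher adjusted over the list alone, among them Fabp4 at 1.43 ± 0.27 (0.70 as the mean over its probe sets) and Adipoq at 1.42 ± 0.33, and no member past the threshold over all genes. Of its 12 members 5 had a negative difference, and the call was lost when camera used ranks (adjusted p = 0.0858). The list of granulosa cell markers was lower (camera adjusted p = 0.0125, median -0.15; adjusted p = 0.563 with an estimated correlation), with 0 of 24 members past the threshold over all genes and, adjusted over the list alone, 1 higher and 2 lower. Without Kras_d26 replicate 2 the granulosa and adipocyte lists did not pass (camera adjusted p = 0.127 and 0.0748, with ranges over all alternatives of 0.00240 to 0.563 and 3.96e-05 to 0.535). The mitosis, DNA replication and oocyte lists had medians of -0.07, -0.06 and -0.03 and did not pass camera at 26 days. The first 2 passed camera as lower without wild type replicate 2 (means of -0.09 and -0.09) and without Kras_d26 replicate 2 (-0.14 and -0.19). The DNA replication mean ran from -0.19 to 0.06 with 1 array left out. With all arrays their adjusted p was 0.127 and 0.167 by camera, and 0.966 for each by fry. In all, 8 of the 20 lists that did not pass did so with some array left out, the others being the oviduct, macrophage, WNT, cholesterol, immediate early and interferon lists. In the lists that did not pass, no member passed over all genes, and adjusted over the list alone the most were 3 higher and 2 lower, in the TGF-beta list.

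The second comparison set the 3-month mutant ovary against the 26-day mutant ovary. Of 33 oocyte genes 31 were lower in the older ovaries and 1 was higher, all 31 mitosis genes were lower, and of 22 macrophage markers 18 were higher and 3 lower. As lists these passed camera, and each call was lost with an estimated correlation (adjusted p = 0.653 for each with an estimated correlation). No list passed under that setting in any comparison. In total 10102 of 18195 genes passed limma's adjusted p of 0.05, 4691 higher and 5411 lower, and 1557 and 2251 of them differed by at least 2-fold. The balance turned with genes below the median level left out, to 3757 higher and 2266 lower. The 3-month arrays had a lower quartile of 40 and 41, against 47 on the 26-day arrays, and a higher 95th percentile. Counts of higher and lower genes therefore depend on the levels tested and are no measure of biology alone. The 18 hybridisation control probe sets, which measure added transcripts and no ovary RNA, were 1.48 log2 units higher on the 3-month arrays. No batch term could be fitted, because each group lies on one side of this difference. Age and array batch therefore cannot be told apart for single genes or for lists. Where the 2 brightest probe sets of a gene both passed, they went the same way in 79.4% of 2979 genes, against 54.1% after shuffling partners. Another choice of probe set (the most variable one or the mean over a gene's probe sets) moved by over 1.5-fold 42 of the 148 genes that passed here among those followed singly (the genes taken by the naming rule and others chosen later), and it ended 4 of their calls. Counts of list members adjusted over the list alone were the same as those over all genes, except for 10 higher granulosa, 28 lower DNA replication, 8 higher and 5 lower p53 target, 8 lower adipocyte and 5 higher cholesterol genes. Members named below as exceptions in their list (Spin1, Kit, Csf1r, Itgam, Cd14, Cd8a, Ms4a1, Epcam and Cdh1), and the plotted genes Zp2, Gdf9 and Top2a, were chosen after their values were seen.

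Oocyte genes fell together at 3 months. In the mutant 31 of 33 measured members were lower, 1 was higher and 1 did not pass (camera adjusted p = 5.04e-10, median -3.52; adjusted p = 0.653 with an estimated correlation). Lhx8, a transcription factor of early oocytes, fell by 5.09 ± 0.52 on the log2 scale. Oosp1 and Omt2b, expressed in oocytes, fell by 4.38 ± 0.50 and 4.27 ± 0.54, and Nlrp14, an oocyte NLR protein, fell by 4.29 ± 0.72 (limma adjusted p of 0.00309 or lower for these 4). The member that rose was Spin1 (0.59, limma adjusted p = 0.00834), and Kit, at -0.12, did not pass. The fall was unequal between the 3-month arrays. Relative to the wild type mean, the median of the oocyte list was -4.27 on replicate 1 and -2.93 on replicate 2. Without Kras_3m replicate 1 Lhx8, Oosp1, Omt2b and Nlrp14 were at -4.17, -3.51, -3.34 and -3.00, and without Kras_3m replicate 2 at -6.01, -5.25, -5.20 and -5.58.

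Cell division genes fell as well. All 31 measured mitosis genes were lower (camera adjusted p = 6.07e-16, median -2.77; adjusted p = 0.653 with an estimated correlation). The checkpoint kinases Ttk and Bub1 fell by 3.65 ± 0.24 and 3.38 ± 0.24, and the spindle motors Kif11 and Kif20a fell by 3.41 ± 0.13 and 3.25 ± 0.13. Of 29 DNA replication genes 26 were lower, 1 was higher and 2 did not pass (camera adjusted p = 3.42e-10, median -1.72; adjusted p = 0.653 with an estimated correlation). Ccne1, the cyclin of S phase entry, fell by 3.39 ± 0.18, and the origin licensing factor Cdc6, Ccne2 and the flap endonuclease Fen1 had differences of -2.79 ± 0.17, -2.71 ± 0.16 and -2.68 ± 0.12. Among cell cycle inhibitors and senescence genes 9 rose, 5 fell and 6 did not pass, and the list did not pass camera (adjusted p = 0.473, with a median of 0.02 and a mean of -0.05). The CDK inhibitor Cdkn2b fell by 2.47 ± 0.18, while Foxo3 rose by 1.40 ± 0.15. Another probe set of Foxo3 passed in the opposite direction. As means over probe sets Ttk was at -2.82, Kif11 at -2.48, Ccne1 at -2.30 and Foxo3 at 0.76. For p53 target genes the counts were 7 higher, 4 lower and 6 not past the threshold (camera adjusted p = 0.188), with Trp53inp1 at 1.17 ± 0.14.

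**Figure D2:**
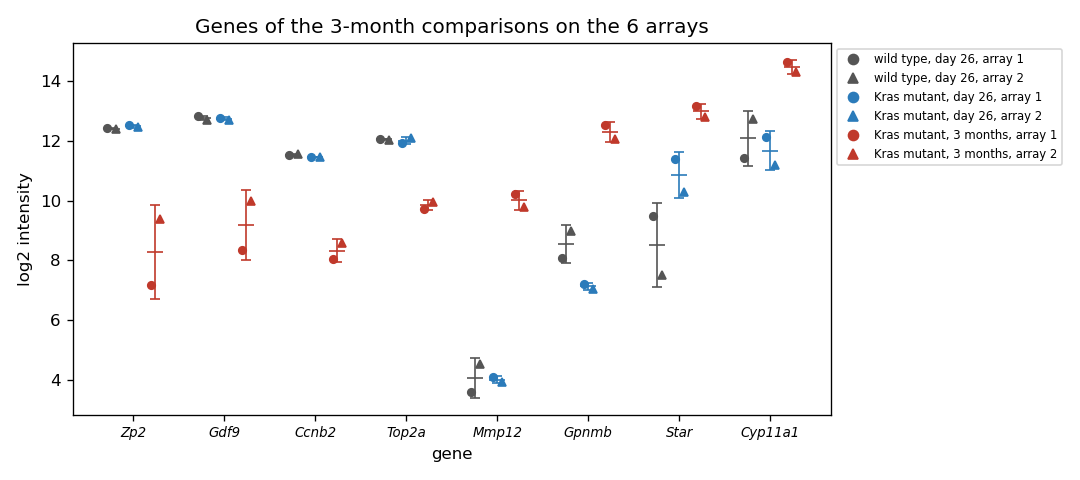
Log2 intensity (vertical axis) of oocyte (Zp2, Gdf9), cell division (Ccnb2, Top2a), macrophage-expressed (Mmp12, Gpnmb) and steroidogenic (Star, Cyp11a1) genes on the 6 arrays; symbols are arrays, horizontal ticks are group means and bars are 1 SD (n = 2). Zp2 lay at intensities of 5425 to 5883 on the 26-day arrays and at 144 and 667 on the 3-month arrays.

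Macrophage markers rose in the 3-month mutant. Of 22 members 18 were higher, 3 were lower and 1 did not pass (camera adjusted p = 7.42e-06, median 2.35; adjusted p = 0.653 with an estimated correlation). Gpnmb, a glycoprotein of lipid-laden macrophages, rose by 5.18 ± 0.30, or 2.32 as the mean over its probe sets, Cd5l by 4.21 ± 0.31, the lysozyme gene Lyz2 12.3-fold and the pore-forming protein gene Mpeg1 10.2-fold. The lower members were the receptor gene Csf1r (-1.10), Itgam (-0.42) and Cd14 (-0.45). For lymphocyte markers 8 were higher, 4 lower and 4 not past the threshold (camera adjusted p = 0.105). Jchain, made by antibody-secreting cells, rose by 4.39 ± 0.21, Il7r by 3.70 ± 0.37, and the T cell receptor chain gene Cd3g by 3.06 ± 0.35, whereas Cd8a lay at -1.60 and the B cell gene Ms4a1 at -1.30. Interferon response genes did not pass as a list (6 higher, 3 lower and 10 not past the threshold, camera adjusted p = 0.188), and Psmb8 and Gbp2 rose by 1.68 ± 0.21 and 1.59 ± 0.29.

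Steroidogenic genes were higher in part at 3 months. In the theca and interstitial list 8 of 14 members were higher and 2 lower (camera adjusted p = 0.146), and in the luteal list 9 of 16 were higher and 2 lower (camera adjusted p = 0.0712). Lists can share members. Of these, 5 theca and interstitial genes and 8 luteal genes are also in another list, so their counts are not independent. Star, which carries cholesterol into mitochondria, had a difference of 2.14 ± 0.65 (limma adjusted p = 0.0294) that passed in 11 of 16 alternatives (limma adjusted p from 0.00489 to 0.192). It did not pass without either Kras_d26 array, without either Kras_3m array or after quantile normalization again. Cyp11a1, which makes pregnenolone from cholesterol, rose by 2.81 ± 0.46, although another probe set of Cyp11a1 passed in the opposite direction. Star ranged from 182 to 725 on the wild type arrays, from 1266 to 2709 on the 26-day mutant arrays and from 7239 to 9254 on the 3-month arrays. Granulosa cell markers went both ways (9 higher, 10 lower and 5 not past the threshold, camera adjusted p = 0.947, with a median of 0.11 and a mean of -0.33). The monoamine transporter gene Slc18a2, the signalling ligand Ihh and the oestrogen receptor gene Esr2 fell by 4.46 ± 0.70, 3.08 ± 0.33 and 1.96 ± 0.28, while Kitl, the KIT ligand, rose by 1.70 ± 0.17. Slc18a2 was at -3.24 without Kras_3m replicate 1 and at -5.68 without Kras_3m replicate 2. Of the ovulation and cumulus expansion genes 6 rose, 2 fell and 14 did not pass (camera adjusted p = 0.309), and the matrix proteoglycan gene Vcan fell by 1.96 ± 0.16. Of 20 cholesterol synthesis and uptake genes 6 rose, 2 fell and 12 did not pass (camera adjusted p = 0.0983), with Srebf2 at 1.59 ± 0.12 and Lss at -3.23 ± 0.35. The means over probe sets were 0.60 for Cyp11a1, -0.75 for Vcan and -0.91 for Lss. On the 3-month arrays this list had medians of 0.99 and 0.08 relative to the wild type mean. Without Kras_3m replicate 2 the luteal and cholesterol lists passed as higher (camera adjusted p = 0.00855 and 7.83e-05, the lowest over all alternatives, the highest being 0.653 and 0.717).

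Epithelial, vascular and stromal lists were mixed at 3 months. Surface epithelium and mesothelium markers had 11 members higher, 6 lower and 5 not past the threshold (camera adjusted p = 0.188). Krt7, Lgr5 and Upk1b rose by 3.41 ± 0.23, 2.27 ± 0.12 and 2.13 ± 0.16, while the epithelial adhesion genes Epcam and Cdh1 lay at -1.67 and -1.33. The oviduct and cilia list was lower (10 of 21 lower and none higher, camera adjusted p = 0.0246; adjusted p = 0.653 with an estimated correlation). Tmem212 and Dynlrb2 fell by 3.45 ± 0.77 and 3.21 ± 0.73, and they also differed between the 2 wild type arrays, by 2.62 and 2.42 log2 units. Neither gene passed without Kras_d26 replicate 2 (limma adjusted p = 0.0851 and 0.0893, the highest over all alternatives, the lowest being 0.000646 and 0.000988), nor without Kras_3m replicate 2. The list's call was lost without Kras_d26 replicate 2 (camera adjusted p = 0.0698) and without Kras_3m replicate 1 (0.0563), and after quantile normalization again (0.0711), with a range over all alternatives of 0.00394 to 0.653. Of 20 endothelial markers 9 were higher and 1 lower (camera adjusted p = 0.0808), with von Willebrand factor, Vwf, at 2.41 ± 0.20. Of 14 smooth muscle markers 9 were lower and 3 higher (camera adjusted p = 0.138), with the coactivator gene Myocd at -2.60 ± 0.37 and Acta2 at -1.20 ± 0.11. Stroma and collagen genes split into 7 higher and 8 lower of 21 (camera adjusted p = 0.947), with Mfap5 at -2.43 ± 0.16. Adipocyte markers had 7 of 12 lower and 1 higher (camera adjusted p = 0.0656), with Pck1, an enzyme of glucose synthesis, at -4.18 ± 0.17 by its brightest probe set. Of 7 erythrocyte genes 4 were lower (camera adjusted p = 0.146). Of 15 Sertoli cell markers 4 were higher and 3 lower (camera adjusted p = 0.355), and Cldn11, a tight junction gene, rose by 3.51 ± 0.32. As means over probe sets Lgr5 was at 1.36, Myocd at -1.63, Acta2 at -0.54 and Pck1 at -1.44. Without Kras_d26 replicate 1 the endothelial list passed as higher and the adipocyte list as lower (camera adjusted p = 0.0473 and 0.0411), and the endothelial list also passed without Kras_3m replicate 2 (0.0202, with ranges over all alternatives of 0.0202 to 0.729 and 0.00594 to 0.653).

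Signalling lists did not pass camera between the mutant ages over all arrays. ERK pathway genes went both ways, with 7 of 27 higher and 10 lower (camera adjusted p = 0.689). The growth factor gene Hbegf and the receptor gene Epha4 fell by 2.32 ± 0.18 and 2.28 ± 0.15. Etv5 was at 1.49 ± 0.14, a call that the mean over its probe sets ended, at 0.25 (limma adjusted p = 0.0929, and 0.000108 to 0.0929 over all alternatives, of which 15 of 16 passed). Epha4 was at -1.45 by the same mean. Of 24 WNT signalling genes 12 were higher and 6 lower (camera adjusted p = 0.0594), and the secreted WNT regulators Sfrp2 and Sfrp4 rose by 4.62 ± 0.18 and 4.38 ± 0.62. The WNT list passed camera as higher without Kras_d26 replicate 1 or Kras_3m replicate 1 (means of 0.90 and 0.86). Over all alternatives its adjusted p ran from 0.0123 by fry to 0.653 by camera with an estimated correlation. Sfrp4 was at 3.31 without Kras_3m replicate 1 and 5.45 without Kras_3m replicate 2. Of 28 TGF-beta family genes 13 were higher and 5 lower (camera adjusted p = 0.165), with Bmp5 at -3.13 ± 0.11, or -1.77 as the mean over its probe sets. Immediate early and heat shock genes had 4 members higher and 7 lower of 23 (camera adjusted p = 0.705), with Atf3 at 1.78 ± 0.14 and Fos at -1.54 ± 0.31. Without Kras_d26 replicate 2 Fos did not pass (limma adjusted p = 0.0570, and 0.00228 to 0.0570 over all alternatives). Of 12 control genes used in every cell 5 were higher and none lower, with a mean difference of 0.21 that became -0.11 after the arrays were quantile normalized again.

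**Figure D3:**
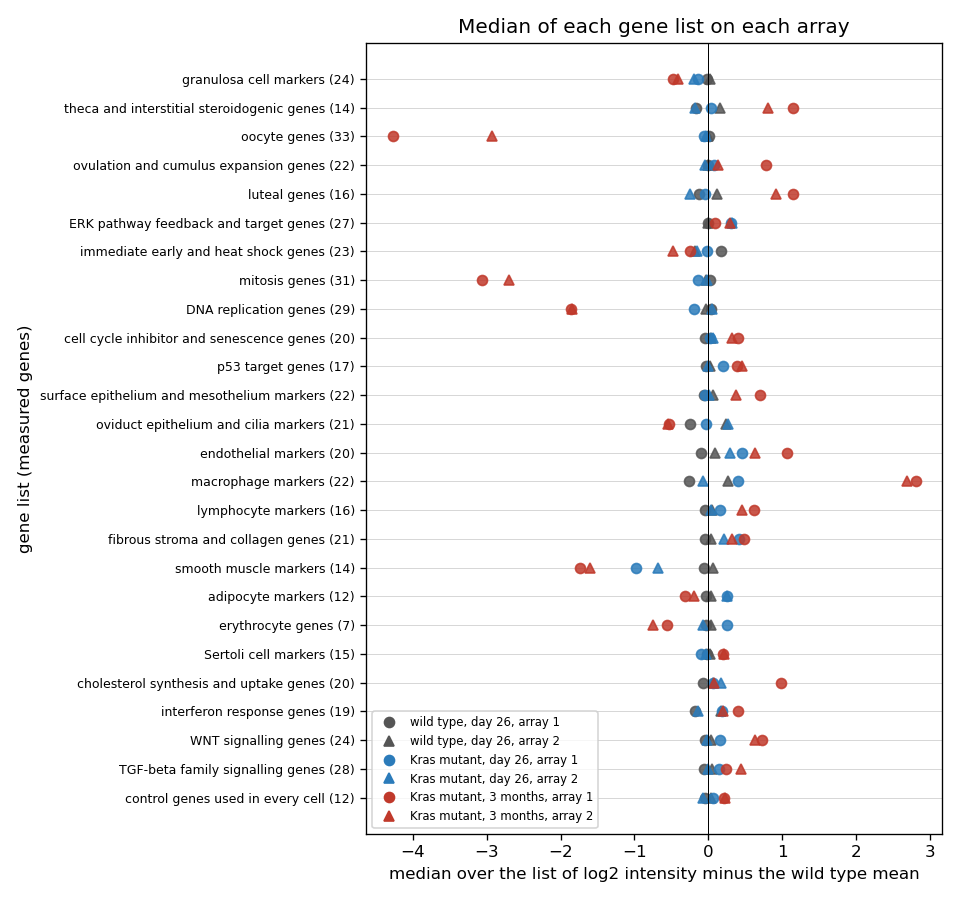
Median over each gene list of log2 intensity minus the wild type mean (horizontal axis) on each of the 6 arrays, with the number of measured genes in brackets. The 3-month arrays lie at -4.27 and -2.93 for oocyte genes, and the 26-day mutant arrays lie at -0.97 and -0.68 for smooth muscle markers.

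By fitted log2 difference, the genes that rose most between the mutant ages included Mmp12, the macrophage metalloelastase (6.01 ± 0.31, limma adjusted p = 4.94e-05), Gpnmb, the collagen gene Col6a5 (4.97 ± 0.26), the transcriptional regulator Zbtb16 (4.89 ± 0.43), the retinol esterifying enzyme Lrat (4.88 ± 0.36), Tmem178 (4.78 ± 0.24), Sfrp2, Jchain, Naip5 (4.38 ± 0.24) and Sfrp4. Those that fell most were Ssc4d, Pramel25, Cryl1, Aif1l, Vwc2, Tfap2c, Ptger3, Tpbpa, Nlrp4a and A2ml1, with log2 differences from -5.60 to -5.10, each with a limma adjusted p of 0.00139 or lower. These sizes and ranks rest on the brightest probe set and on single arrays, with Pramel25 at -4.19 and Nlrp4a at -4.29 without Kras_3m replicate 1. As means over probe sets Zbtb16 was at 3.08, Lrat at 4.18, Cryl1 at -1.28, Aif1l at -2.93, Vwc2 at -2.81, Tfap2c at -2.34, Ptger3 at -3.35 and Tpbpa at -1.71. Low levels were not checked against background, and 24 of these 148 singly followed genes had a lower group below the lower quartile of its arrays, with mean intensities such as 16.0 for Mmp12, 12.8 for Col6a5, 11.2 for Vwc2 and 15.5 for A2ml1. The others named here were Sfrp2, Jchain, Naip5, Pramel25, Tfap2c, Tpbpa, Nlrp4a, Lhx8, Tmem212, Dynlrb2, Cd5l, Il7r, Cd3g and Cldn11. The sizes and ranks of such differences are uncertain, and with 16 added before log2, an alternative chosen after the data were seen, Mmp12 was at 5.03, Col6a5 at 3.86, Sfrp2 at 4.07, Jchain at 3.52, Cd5l at 3.66, Il7r at 3.14, Cd3g at 2.36, Lhx8 at -4.28, Vwc2 at -4.10 and A2ml1 at -4.12.

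The third comparison set the 3-month mutant against the 26-day wild type, and it joins genotype, age and array batch, which this design cannot separate. Here 10614 genes passed limma's adjusted p of 0.05, 4979 higher and 5635 lower, a balance that turned to 3910 higher and 2351 lower with genes below the median level left out. The ERK list went both ways (11 of 27 higher and 8 lower, camera adjusted p = 0.317), with a median of 0.27. Among its members Dusp6 and Dusp4 were 7.47-fold and 7.17-fold higher, Etv5 was at 3.49, or 1.54 as the mean over its probe sets, and Hbegf was at -2.55 ± 0.18. The endothelial list was higher (12 of 20 higher and 1 lower, camera adjusted p = 0.00155; adjusted p = 0.585 with an estimated correlation), with Vwf at 2.92 ± 0.20 (camera adjusted p = 0.149 with dim genes left out, and 0.000222 to 0.585 over all alternatives). The smooth muscle list was lower (11 of 14 lower and 1 higher, camera adjusted p = 0.00242; adjusted p = 0.585 with an estimated correlation), with Cnn1 at -3.18 ± 0.17. The WNT list was higher (14 of 24 higher and 4 lower, camera adjusted p = 0.0125; adjusted p = 0.585 with an estimated correlation). Its members Sfrp2 and Wnt2 were at 4.84 ± 0.18 and 4.03 ± 0.37, over wild type means of 27.6 and 33.2 below the lower quartile, and at 4.20 and 3.51 with 16 added before log2. Wnt2 was at 4.65 without Kras_3m replicate 1 and at 3.41 without Kras_3m replicate 2. Mitosis (31 of 31 lower), DNA replication (28 of 29), oocyte (32 of 33) and macrophage genes (18 of 22 higher) passed with camera adjusted p of 8.72e-06 or lower. All of these 7 calls were lost with an estimated correlation (adjusted p = 0.585 for each with an estimated correlation). Adjusted over the list alone, the counts of these lists were the same, except for 19 higher macrophage and 12 higher ERK genes. The rule for named genes also takes Clec1b, a C-type lectin-like receptor gene (6.62 ± 0.35), Mmp12, Col6a5, the glutathione transferase gene Gsta3 (5.16 ± 0.18) and Gpr182 (5.14 ± 0.11) as higher. Wild type intensities were below the lower quartile for Clec1b, Mmp12, Col6a5 and Gpr182 (27.5 for Clec1b), so these sizes are uncertain, and Clec1b was at 5.97 with 16 added before log2 and at 7.22 without Kras_3m replicate 1. Ssc4d was 46.6-fold lower, Cryl1 and Aif1l were at -5.58 and -5.40, and Pramel25 and Tfap2c, at -5.63 and -5.42, ended below the lower quartile of the 3-month arrays, with Pramel25 at -4.30 without Kras_3m replicate 1. The means over probe sets were -1.65 for Cryl1, -3.23 for Aif1l and -2.30 for Tfap2c.

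All 5 genes that passed at 26 days also passed, in the same direction, in the 3-month mutant against the wild type. Independent lists of these sizes would share 1.44 genes in the same direction. Simulated unchanged groups with the same shared wild type arrays gave 0.25 and 0.18 calls on average and shared 0.02, so that count is fixed near 0 and is no measure for the 5. The Pearson correlation of log2 differences across genes, which are not independent replicates, was 0.425, below the simulated 0.4995, and the covariance was 0.107, against 0.0147 in the simulation. The wild type arrays were not split between the 2 comparisons. The simulation counts their sharing at the fitted spread only, so part of the excess may come from them if samples vary more. For the 26-day comparison and the one between mutant ages, shared 26-day mutant arrays alone gave a simulated covariance of -0.0147. The measured covariance was 0.0512, with 4 genes called in the same direction and 0 in the opposite. This does not settle the source, because the simulation drew each gene by itself while replicates also differed jointly along these axes. The slope of Kras_d26 replicate 1 minus replicate 2 on the difference of 3-month mutant and wild type was 0.095. For wild type replicate 2 minus replicate 1 on the difference between mutant ages it was 0.045. A chance position of the few samples along these axes is not covered. Between the mutant ages, Dusp4 and Clec14a rose further by 0.97 ± 0.16 and 0.56 ± 0.14, Etv5 was at 1.49 ± 0.14 but at 0.25, not past the threshold, as the mean over its probe sets, Lmod1 fell further by 0.44 ± 0.11, and Stc1, at -0.26 ± 0.13, did not pass (limma adjusted p = 0.121).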

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

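The tests in this part were chosen after the results were seen, except the repeated quantile normalization, which was planned. 2 sets of control probe sets, outside the comparisons, were brighter on the 3-month arrays than on the wild type arrays. The 18 hybridisation controls, transcripts added to each array, were 1.47 log2 units (2.78-fold) higher on the 3-month arrays than on the wild type arrays, while the 4 26-day arrays spanned 0.17 units. The 24 labelling controls, added before labelling, were 0.33 units higher, while the 26-day arrays spanned 0.24 units. The 9160 probe sets without a listed gene, which entered only the alternative that tests all probe sets, went both ways, with 2794 higher in the 3-month mutant than in the wild type and 1979 lower.

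The first pattern is the difference of 10102 genes between the mutant ages. An array batch acting on each probe set by itself would leave probe sets of 1 gene unrelated, but they went the same way in 79.4% of genes where both passed, above the 52.4% to 55.7% after shuffling. A batch that ignores cell type would leave fixed lists near random lists of equal expression, but the medians of the oocyte (-3.52), mitosis (-2.77) and DNA replication (-1.72) lists lay below all 10000 random lists and that of the macrophage list (2.35) above all, while the oviduct and cilia list (-0.59) lay below 98.2% of them, too near to decide. The wider spread of values on the 3-month arrays is not the whole cause either, since 9266 genes passed after the arrays were quantile normalized again, 8400 of them shared with the main result. Random lists were drawn gene by gene, while the genes of these lists vary together (estimated correlations of 0.430 to 0.675). The test with random lists does not cover a batch that moves such genes together. For single genes and for lists, an array batch therefore cannot be told apart from age. No 3-month wild type was analysed here, and the hybridisation controls differ by 1.48 log2 units between the same arrays.

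The second pattern is the lower smooth muscle list in the 26-day mutant, with a median of -0.81. Less attached oviduct, whose wall is muscular, would lower oviduct markers too, but their median in the mutant was 0.12 (SD of members 0.43), above the smooth muscle median by more than that SD. With each 26-day array left out the oviduct median ran from -0.14 to 0.42. It stayed above the smooth muscle median by 0.70 to 1.19, each time by more than the SD of its members (0.26 to 0.86). Between the wild type arrays the oviduct list differed by a median of 0.49 (SD 0.94) and the smooth muscle list by 0.12 (SD 0.19). Without wild type replicate 1, 17 of 21 oviduct members were lower in the mutant, and without wild type replicate 2, 3 were. The SD is a spread over members, not of the median between arrays, so some loss of attached oviduct is not excluded. The oviduct list holds markers of epithelium and cilia, so a change in the muscle of attached oviduct alone would not show in it. Attached muscle of the hilum or ligaments also remains open. Adipocyte markers, another tissue of the surroundings, had a median of 0.19 and a mean of 0.50 in the mutant. The list passed camera as higher (adjusted p = 0.000795), but 5 of its 12 members had a negative difference and the call was lost with ranks. Fat and muscle need not be trimmed together, so this does not decide. A change within the mutant ovary stays an untested hypothesis.

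The third pattern is a set of clock output genes on the 3-month arrays, of which 9 of 11 rose against the 26-day mutant (median 1.90). Per1 rose by 1.93, Per3 by 2.46 (1.71 as the mean over its probe sets and 3.72 with the most variable one) and Dbp by 2.40 (3.19 with the most variable one), while Nr1d2, at 1.86, turned with other probe sets. If the ovaries had been taken at another phase of the day, genes of the opposite phase should be lower. Their median was -0.37, with 2 of 4 past the threshold as lower. Clock lay at -3.97, while Arntl, Nfil3 and Npas2 lay at -0.44, -0.31 and 0.12. This list is too short and too uneven (SD 1.90) to decide, so collection time, age and array batch cannot be told apart.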

How the results depend on the processing

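The 26-day count of 5 genes depended on the processing, and the 3-month counts did so less. Against wild type at 26 days, limma called 0 genes without each of the 6 arrays in turn (0 to 0, with 832 to 1710 at an unadjusted p under 0.05), 0 with only the arrays of the 2 groups (1710 at an unadjusted p under 0.05), 0 when all probe sets were tested (2950 unadjusted) and 0 at an adjusted p of 0.01 (1400 unadjusted). It called 21 with a mean-variance trend, 16 with genes below the median level left out (fewer genes tested), 8 with the mean of probe sets, 3 with the most variable probe set and 3 after quantile normalization again. With 16 added before log2, an alternative chosen after seeing the data, it called 14. The 5 genes were all among the 21 and among the 14, and 4 of them were among the 16. Leaving out either 3-month array changes no 26-day difference and gives the same fit as only the arrays of the 2 groups. These settings are thus the same check, on fewer residual degrees of freedom. Except where noted, the cause was not tested. The genes shared by this comparison and the 3-month mutant against wild type, 5 in the main result, numbered 19 with the trend, 15 with the filter, 0 at an adjusted p of 0.01 and 0 without each array (0 to 0).

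Replicate numbers do not pair the samples: deviations of same-numbered arrays correlated at -0.15 (wild type and 26-day mutant), -0.07 (wild type and 3-month mutant) and 0.05 (both mutants) across genes. With the replicate block the 26-day count was 0 (1243 unadjusted), the genes shared between comparisons 0, and the gene lists past the test for the mutant ages 8. The 3-month counts with the block were 9492 and 10124. With crossed numbers as the block, added after seeing the data, the 26-day count was also 0 (1458 unadjusted).

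The count for the mutant ages was 6023 with the filter (62.4% higher, against 46.4% in the main result), 23157 with all probe sets and 3808 with a 2-fold minimum. The count for the 3-month mutant against wild type was 6261 (62.5% higher, against 46.9%), 24433 and 4309 under the same 3 settings. Fewer or more features were tested in the first 2, and the third adds a criterion. Without single arrays the counts ran from 6934 to 9282 and from 8075 to 9959. Gene lists past the test numbered 0 in each comparison with an estimated correlation, a setting that rests on 3 residual degrees of freedom. They numbered 2, 14 and 15 with fry, which does not compare a list with other genes. Without single arrays they numbered 6 to 13 at 26 days (13 without wild type replicate 2) and 4 to 8 for the mutant ages (8 without Kras_d26 replicate 1 or Kras_3m replicate 2). At 26 days the immediate early list had means from -0.24 to 0.20, and the interferon list from -0.25 to 0.29, when each array was left out, with opposite calls without each wild type array.

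Among named genes, Polr2a turned from 0.73 to -0.55 with the mean of probe sets and -1.84 with the most variable one between mutant ages, and from 0.83 to -0.56 and -1.94 against wild type. Nr1d2 turned from 1.86 to -0.0616 and -1.99 between mutant ages, and Car3 from 1.08 to -2.18 with the most variable probe set against wild type. The 5 genes called at 26 days each kept their direction in all alternatives, with log2 differences of 1.29 to 2.16 for Etv5 and -2.02 to -1.05 for Stc1. Of 110 genes named and called for the 3-month mutant against wild type 9 lost their call in some alternative, and of 148 for the mutant ages 23 did. Star between the mutant ages passed in 11 of 16 alternatives, with adjusted p up to 0.192. No detection calls were used, so signal over background was not judged gene by gene.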

Other observations

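The lists of antigen presentation, glucocorticoid-responsive and retinoid genes and all comparisons in this part were chosen after the values were seen. Antigen presentation genes, most of them of MHC class II, were higher in the 3-month than in the 26-day mutant for 7 of 9 measured genes and lower for none. H2-Aa, H2-Ab1 and the invariant chain gene Cd74 rose by 3.70, 3.27 and 2.96 on the log2 scale (limma adjusted p of 9.65e-05 or lower), while the costimulatory gene Cd80 did not pass. Genes that glucocorticoids induce in many tissues were higher for 8 of 12 and lower for 1. Zbtb16, Ddit4 and Mt2 rose by 4.89, 2.83 and 2.26, Fkbp5 rose by 1.87, and Pdk4 fell by 1.53. As means over probe sets Zbtb16 was at 3.08 and Fkbp5 at 0.82. Retinoid genes went both ways (5 higher and 3 lower of 11), with Lrat at 4.88 and the retinol-binding protein gene Rbp4 at -2.42. These differences carry the same array and age limits as the comparison they come from.

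Clec1b, Gpr182 and Wnt2, chosen after their values were seen, were higher on each 26-day mutant array than on the wild type arrays and higher again on each 3-month array. Clec1b had intensities of 26 and 29 in the wild type, below the lower quartile, 145 and 134 in the 26-day mutant and 1780 and 4093 in the 3-month mutant. Its 26-day difference of 2.34 ± 0.35 did not pass (limma adjusted p = 0.146). Gpr182, a receptor of endothelial cells, read 48 and 45, then 99 and 108, then 1588 and 1684 (26-day difference 1.15 ± 0.11, limma adjusted p = 0.0643). Wnt2 read 38 and 29, then 140 and 138, then 353 and 833 (26-day difference 2.07 ± 0.37, limma adjusted p = 0.197).

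The 2 ovary samples of 3 months differed from each other in sets of genes. Of 33 oocyte genes 32 were lower on replicate 1, by a median of 1.22 log2 units, and 30 of 31 mitosis genes were lower there by 0.37, while DNA replication genes differed by a median of -0.09. All 20 measured cholesterol synthesis and uptake genes were higher on replicate 1, by a median of 0.78. The SD of the difference over all genes was 0.33. With 1 array each, these differences have no replicate check.

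Among the 26-day arrays, Kras_d26 replicate 1 lay nearest the 3-month arrays (Pearson correlations across genes, which are not independent replicates, of 0.930 and 0.938, against 0.907 to 0.924 for the other 26-day arrays). Ovgp1 read 107 and 1050 on the wild type arrays, 391 and 1034 on the 26-day mutant arrays and 212 and 77 on the 3-month arrays.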
